A study of Rattus norvegicus with 30 samples.

How the data were processed

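Liver RNA from 30 male F344 rats was profiled, 1 array per animal, on an Affymetrix whole-genome rat array. Per the labels, the animals were 3 months (young) or 24 months (old) of age and received a control diet or the same diet with 0.2% R-α-lipoic acid in a modified pair-feeding scheme of 2 weeks. The labels' protocols name a column kit for the extraction of total RNA and biotinylated cRNA made by the standard procedure of the manufacturer. Groups held 8 young control, 8 young LA, 8 old control and 6 old LA animals, and the numbers of the last group skip the 2 animals that died. Groups and numbers were taken from the sample titles. The numbers were not read as pairs in the main fit, since the labels do not say what they mark or which animals were pair-fed partners, and a fit with the number as a block was planned as an alternative. Times of tissue collection and of the last meal were not given in the sources used here.

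The deposited table holds log2 values per probe set. Per the submitters' processing notes the authors used GCRMA, which corrects probe signals for background from probe sequence, normalizes between arrays and summarises each probe set. Its version and any further filter were not given in the sources used here. The log2 unit was checked from the range of the values on each array. The table held 31099 probe sets, of which 20826 listed 1 gene, 436 several genes, 9780 no gene and 57 were controls. Gene symbols came from the table pairing probe sets with genes, and the RefSeq table, made on assembly GRCr8, served for identifiers and synonyms alone. Of the probe sets with 1 gene, 20764 had a current RefSeq identifier, and they covered 14218 genes.

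Probe sets with a log2 value over 4 on at least 6 arrays were kept (19762, of which 15012 listed 1 gene), since 6 is the size of the smallest group. The probe set with the highest mean over the 30 arrays stood for its gene, which left 10869 genes, and 3050 genes had more than 1 probe set past the filter. A log2 value of 4 was taken as the floor of the signal. Where the dimmer group of a comparison had a mean under 4, the fold was computed against 4 and is given as a lower bound. Arrays have no read depth, and the precision rests on signal over background and on the spread between animals: 60.5% to 62.8% of the probe sets of an array exceeded 4.

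All arrays entered 1 linear model with 4 groups in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 26 residual and 2.54 prior degrees of freedom. Contrasts were old minus young on each diet, LA minus control at each age, the difference of the 2 LA effects (interaction) and their mean. Adjusted p values are Benjamini-Hochberg values within a contrast, called under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. These choices, the gene lists and the rule for named genes were fixed before the data were examined.

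Gene lists numbered 35 with 633 entries, of which 507 were measured. They covered the clock (Bmal1 phase; Per and Dbp phase), fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPARα targets, gluconeogenesis and fasting, amino acid catabolism and urea cycle, NRF2 targets and glutathione, xenobiotic P450 and nuclear receptors, male-predominant and female-predominant liver genes, and bile acid synthesis and transport. Further lists were acute-phase proteins, chemokines and inflammatory signals, interferon-stimulated genes, MHC class II, cell cycle, p53 targets and senescence, oxidative phosphorylation, lipoate synthesis and lipoylated complexes, ER stress and chaperones, cytosolic heat shock proteins and metal handling. Cell type markers were hepatocyte, Kupffer cell and macrophage, T and NK cell, B and plasma cell, stellate cell and matrix, bile duct and progenitor, endothelium, erythroid cell and blood, exocrine pancreas and adipocyte. Neutrophil and skeletal muscle lists had fewer than 4 measured genes and were not tested. Inflammation, lipid synthesis and circadian rhythm are themes of the series title, so those lists are not an independent choice. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 33 lists of a contrast, and beside it camera with an estimated correlation and fry. Members were also adjusted over their list alone.

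Named genes were, per contrast, the 10 with the largest positive and the 10 with the largest negative difference among those called (5 each way for the interaction), without placeholder symbols. Added were up to 4 members with the smallest p of each list described, and Bmal1, Npas2, Per2, Dbp, Nr1d1, Srebf1, Fasn, Acaca, Elovl6, Cd74, Cyp2c11 and Cyp2c12 in each contrast.

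Agreement between contrasts was measured as Pearson r across genes and as shared calls against the number expected from independent lists. For the LA effect in old animals against the age effect, which share the old controls, 100 simulations without effects and 70 splits of the old controls were run. Spread between animals was compared by exact permutation of the group labels over distances computed once in the real groups. RNA quality was the mean difference between 5′ and 3′ control probe sets of Gapdh and beta-actin.

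The model was tested on simulated data after a first fit of the real arrays and was not changed by the test. In it 50 genes per step were moved by a log2 change of -2, -1, 1 or 2 among 10869. In age on the control diet 48, 44, 46 and 48 of 50 were recovered, and 10 unchanged genes were called (5.10% of the calls). For LA in young animals it was 50, 45, 44 and 49 of 50, with 7 unchanged genes called (3.59%). For LA in old animals it was 47, 41, 44 and 50 of 50, with 90 unchanged genes called (33.1%). For age on the LA diet it was 49, 37, 42 and 50 of 50 with 18 (9.18%), for the interaction 48, 33, 39 and 47 with 21 (11.2%), and for the mean LA effect 50, 42, 49 and 50 with 20 (9.48%).

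Alternatives were no filter, a filter at 6, all probe sets, the mean of a gene's probe sets, a second quantile normalization, centring each array on its median, eBayes with trend and robust, array weights, only the groups of a contrast, the replicate number as a block, RNA quality as a covariate and leaving out each array in turn. Leaving out old control 5 and old LA 2 together, and raising values under 4 to 4, were chosen after seeing the data, as was leaving out each array in turn for the spread between animals. Leaving out old control 1 and 7 together was also run once and then dropped, since these arrays had been picked by their clock genes, and its counts are not reported here. Splits of the animals numbered 100 per contrast, the real one included.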

Results

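Hepatic gene expression was measured in male F344 rats, an inbred strain used in ageing research, at 3 and 24 months of age. Young and old animals ate a purified diet, plain or supplemented at 0.2% by weight with the R form of α-lipoic acid (LA), for 2 weeks. Lipoic acid is a dithiol cofactor of mitochondrial dehydrogenase complexes and is also taken as a supplement. Total RNA from the median liver lobe of each animal was hybridised to 1 whole-genome Affymetrix rat array, which gave 30 arrays: 8 young control, 8 young LA, 8 old control and 6 old LA, the last group having lost 2 animals. The values were GCRMA log2 intensities. Array medians lay between 5.20 and 5.46, and 60.5% to 62.8% of the probe sets exceeded a log2 value of 4. No arrays held identical values. The first principal component carried 50.4% of the variance, and old control 5 (score 112) and old LA 2 (score 78.2) lay farthest from the other arrays. Differences below are log2 values ± SE from limma over 10869 genes, with Benjamini-Hochberg adjusted p, for groups of n = 8, 8, 8 and 6 in the order above.

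The comparison of old with young animals on the control diet asks how ageing changes liver transcripts. Genes with male-predominant expression lost most of their signal in old livers, and several genes with female-predominant expression gained signal. Hsd3b5, a steroid-metabolising enzyme of the male rat liver, was at least 449-fold lower in old animals, falling from 12.81 ± 0.24 to 2.15 ± 0.18 (SD, n = 8 each). Cyp2c12, the female-specific P450, rose by 7.48 ± 0.29, from 7.59 ± 0.56 to 15.08 ± 0.62 (SD). Akr1b7, an aldo-keto reductase, was at least 519-fold higher. Among 10 measured male-predominant genes, 9 fell, including the male-specific P450 genes Cyp2c11 (-7.66 ± 0.73) and Cyp3a2 (-7.99 ± 0.42), Obp3, which encodes a secreted lipocalin (-9.42 ± 0.36), and Stac3 (-7.21 ± 0.39). Of 8 measured female-predominant genes, 6 rose, among them A1bg (at least 36.1-fold), Prlr, the prolactin receptor (4.92 ± 0.40), and the hydroxysteroid sulfotransferase Sult2a2 (5.47 ± 0.52), and 1, the organic anion transporter Ust5r, fell by 5.95 ± 0.29. Both lists also shifted with an estimated correlation (adjusted p = 0.00105 for the male and 0.0268 for the female list). With adjustment over the list alone, 9 male-predominant genes fell, and 7 female-predominant genes rose.

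Genes outside these lists also differed with age. Sult1e1, the oestrogen sulfotransferase, fell by 9.37 ± 0.46. Slc22a8, an organic anion transporter, was at least 172-fold lower, and Akr1c3, an aldo-keto reductase, was at least 49.4-fold lower. Inmt, an N-methyltransferase, fell by 6.10 ± 0.51. The lipases Pla1a and Pnliprp2 were higher, Pla1a by 4.71 ± 0.43 and Pnliprp2 at least 15.0-fold. Tsx rose by 4.95 ± 0.74. In all, limma called 3911 of 10869 genes, 2207 higher and 1704 lower in old animals, and 820 of them exceeded 2-fold (654 higher, 166 lower). Centring each array on its median moved the median age difference of all genes by -0.11 and turned the split of calls to 1681 higher and 2844 lower of 4525, so the direction of small differences depended on the scaling. Taking probe sets in place of genes as genes changed with age, control diet, gave 6130 calls among 19762 probe sets.

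**Figure D1:**
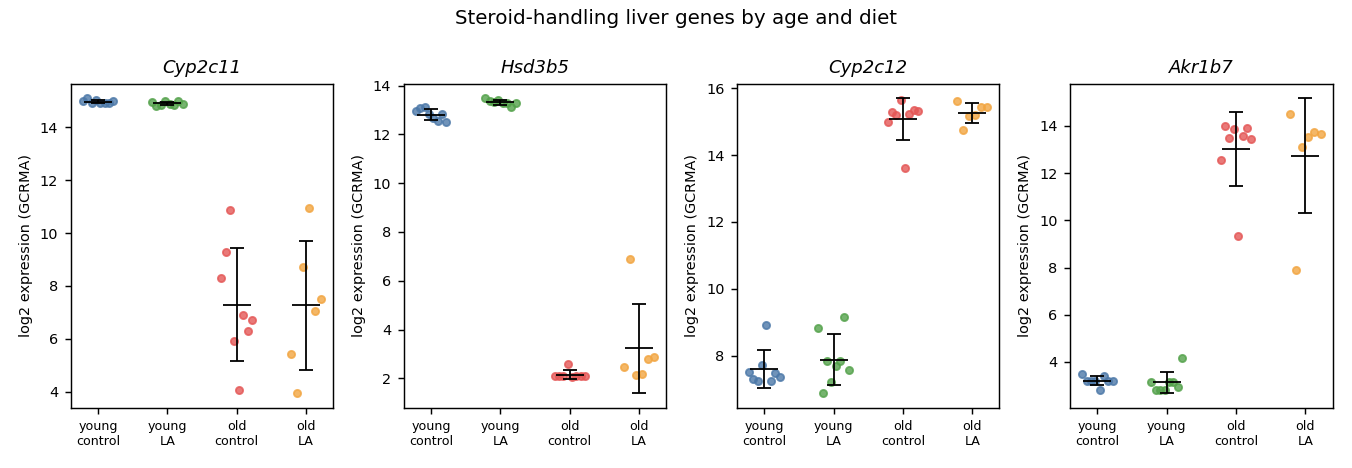
Log2 expression of 4 steroid-handling genes on each array (points) with the group mean and SD (black). Cyp2c11 and Hsd3b5 lie lower, and Cyp2c12 and Akr1b7 higher, in all old than in all young groups by mean, at both diets.

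Many immune and inflammatory genes were also higher with age. Their lists and the cell cycle list passed with preset correlation and none of them with an estimated one (adjusted p = 0.209 to 0.506). With fry, which compares the members with no change and not with other genes, they passed (adjusted p = 2.74e-07 to 0.0295). The inflammation theme is named in the series title and is not an independent choice. Of 18 measured T and NK cell genes, 13 rose, 14 when adjusted over the list alone, including Cd8a, a lymphocyte co-receptor (4.14 ± 0.58), the granzyme Gzmk (4.70 ± 0.80) and the signalling chain Cd247 (2.94 ± 0.54). The score of this list was uneven among old animals, with 3.63 in old control 5 and 2.72 in old control 7 against -0.52 in old control 8. Cell cycle genes, of which 12 of 25 rose (17 adjusted over the list alone, 7 without young control 4 or 7, and 5 without old control 5, 6 or 7), had the highest control scores in the same livers, 2.36 in old control 5 and 1.89 in old control 7. The replication helicase subunit Mcm2 rose by 1.23 ± 0.30, and the topoisomerase Top2a rose at least 4.21-fold.

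**Figure D2:**
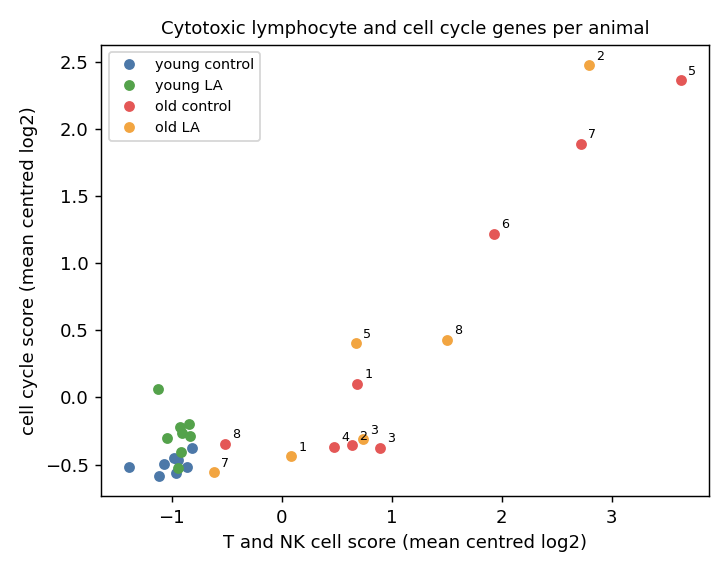
T and NK cell score (horizontal) against cell cycle score (vertical) of each array, by group. Both scores were highest in a few old animals, with young animals near the lowest values of both.

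Chemokine and inflammatory signal genes rose in 16 of 26 cases (16 adjusted over the list alone), such as Ccl5 (3.49 ± 0.67), Cxcl16 (1.62 ± 0.31), the adhesion molecule Icam1 (1.22 ± 0.21) and Tnfaip3, a brake on NF-κB signalling (2.95 ± 0.44). Interferon-stimulated genes rose in 17 of 26 cases, also when adjusted over the list alone, and these included the immunoproteasome subunits Psmb10 (1.42 ± 0.13) and Psmb9 (1.56 ± 0.17). Kupffer cell and macrophage markers rose in 12 of 16 cases (12 adjusted over the list alone), with Gpnmb, a glycoprotein of lipid-laden macrophages, at 2.66 ± 0.36 and the lysozyme Lyz2 at 0.84 ± 0.15. MHC class II genes rose in 7 of 11 cases (9 adjusted over the list alone, and 4 without old control 5), for example Cd74, the invariant chain (1.20 ± 0.38), and the lysosomal proteases Lgmn (1.51 ± 0.27) and Ctss (0.99 ± 0.28).

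Acute-phase genes rose in 11 of 20 cases and fell in 1 (0 without any young control but 5, or without old control 5, 6 or 8), the same counts as when adjusted over the list alone, with the lipopolysaccharide-binding protein Lbp at 2.47 ± 0.23 and ceruloplasmin, Cp, at 0.42 ± 0.06. Bile duct and progenitor markers rose in 7 of 9 cases (7 adjusted over the list alone), led by the tight junction gene Cldn7 (at least 11.6-fold) and Cd24 (3.15 ± 0.60). Each of these immune and cell type lists passed with fry, but none with an estimated correlation. The adjusted p with an estimated correlation was 0.209 for the T and NK cell, interferon, chemokine, acute-phase and bile duct lists. For the Kupffer cell list the adjusted p was 0.300 with an estimated correlation, for MHC class II 0.477 and for the cell cycle 0.506. Stellate cell genes (6 of 19 higher), endothelial genes (3 of 12 higher), B and plasma cell genes (2 of 5 higher, and 1 without young control 4 or old control 1, 2 or 7) and erythroid genes (1 of 4 higher) were not shifted as lists with camera at preset correlation, with adjusted p = 0.103, 0.0691, 0.230 and 0.242. With fry the B and plasma cell (adjusted p = 0.000336) and erythroid (adjusted p = 0.0295) lists passed, and the stellate cell and endothelial lists did not. Hepatocyte markers were not shifted either (adjusted p = 0.242, mean difference -0.10).

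Metabolic genes moved in both directions with age. Over all 33 lists of this contrast, fry called 24, where camera called 20 with preset and 2 with an estimated correlation. Cholesterol synthesis genes rose in 14 of 20 cases (16 higher and 1 lower adjusted over the list alone), including squalene epoxidase, Sqle (2.69 ± 0.32), and Idi1 (1.60 ± 0.32), with adjusted p = 0.436 with an estimated correlation. Oxidative phosphorylation genes fell in 21 of 29 cases (27 adjusted over the list alone) by small amounts, such as Ndufb3 (-0.50 ± 0.07) and Cyc1 (-0.37 ± 0.07), with adjusted p = 0.223 with an estimated correlation. Amino acid catabolism genes fell in 11 of 19 cases, also when adjusted over the list alone, and in 7 without old control 1. Among these were serine dehydratase, Sds (-3.98 ± 0.98), the alanine aminotransferase Gpt (-1.32 ± 0.21), Tdo2 (-0.47 ± 0.11) and Oat (-0.91 ± 0.22), and the list had adjusted p = 0.220 with an estimated correlation. The sterol exporter Abcg5 fell by 4.49 ± 0.50 and its partner Abcg8 was at least 3.13-fold lower, and their bile acid and transport list had 6 genes lower and 1 higher of 17 (2 higher without old control 5, the same adjusted over the list alone, and adjusted p = 0.481 with an estimated correlation). NRF2 target genes rose in 9 and fell in 3 of 20 cases, the same adjusted over the list alone, with the glutathione transferase Gsta3 at least 35.1-fold higher, the quinone reductase Nqo1 at 2.64 ± 0.25 and the efflux pump Abcc3 at 4.31 ± 0.45 (adjusted p = 0.223 with an estimated correlation).

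Xenobiotic P450 and receptor genes fell in 7 and rose in 1 of 15 cases, also when adjusted over the list alone (2 higher without old control 5), with Cyp3a18 at -2.07 ± 0.23 (adjusted p = 0.235 with an estimated correlation). Genes of lipoate synthesis and the lipoylated complexes fell in 6 and rose in 1 of 14 cases (7 lower adjusted over the list alone, and adjusted p = 0.385 with an estimated correlation). Targets of p53 rose in 5 of 13 cases (5 higher and 1 lower adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 2.70 ± 0.39 and the cyclin Ccng1 at 1.13 ± 0.12, and adjusted p = 0.280 with an estimated correlation. Cela1, an elastase, fell by 3.16 ± 0.44, and its exocrine pancreas list had 3 of 5 genes lower (3 adjusted over the list alone, 1 without old control 5 or 6, and adjusted p = 0.223 with an estimated correlation). Clock genes of the Per and Dbp phase fell in 4 of 11 cases (5 adjusted over the list alone), among them Per2 (-1.25 ± 0.40), Tef (-1.61 ± 0.26) and Usp2 (-1.32 ± 0.39), with adjusted p = 0.300 with an estimated correlation. Bmal1 and Npas2, activators of the clock, rose, Bmal1 by 1.76 ± 0.45 and Npas2 at least 4.84-fold, while Dbp (-1.51 ± 0.60, adjusted p = 0.0509) and Nr1d1 (-0.46 ± 0.60, adjusted p = 0.567) did not pass. The clock genes of old control 1 and 7 lay near those of LA-fed animals, with Bmal1 at 8.08 and 8.20 against a young control mean of 4.35 ± 0.87 (SD).

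Fatty acid and triglyceride synthesis genes were not shifted as a list (adjusted p = 0.911, with 4 higher and 3 lower of 24, the same adjusted over the list alone, and 8 higher without old control 5). Fatty acid synthase, Fasn, rose by 1.70 ± 0.55, whereas Srebf1 (0.05 ± 0.33, adjusted p = 0.923), Acaca (0.61 ± 0.36, adjusted p = 0.177) and Elovl6 (0.97 ± 0.60, adjusted p = 0.200) did not pass. The lists of gluconeogenesis and fasting, heat shock proteins, metal handling and the Bmal1 phase did not pass either with camera at preset correlation, with adjusted p = 0.108, 0.307, 0.847 and 0.242. Of these, gluconeogenesis and fasting (adjusted p = 0.000561) and the Bmal1 phase (adjusted p = 0.0205) passed with fry. Signs of median, mean and test differed for 3 lists that did not pass. ER stress genes had a median of -0.15, a mean of 3e-04 and a negative test (adjusted p = 0.192), and the mean turned to -0.11 with median-centred arrays. Adipocyte genes had a median of 0.37 and a mean of 0.14 with a negative test (adjusted p = 0.911). Fatty acid oxidation genes had a median of -0.04 and a mean of 0.24 with a negative test (adjusted p = 0.911).

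**Figure D3:**
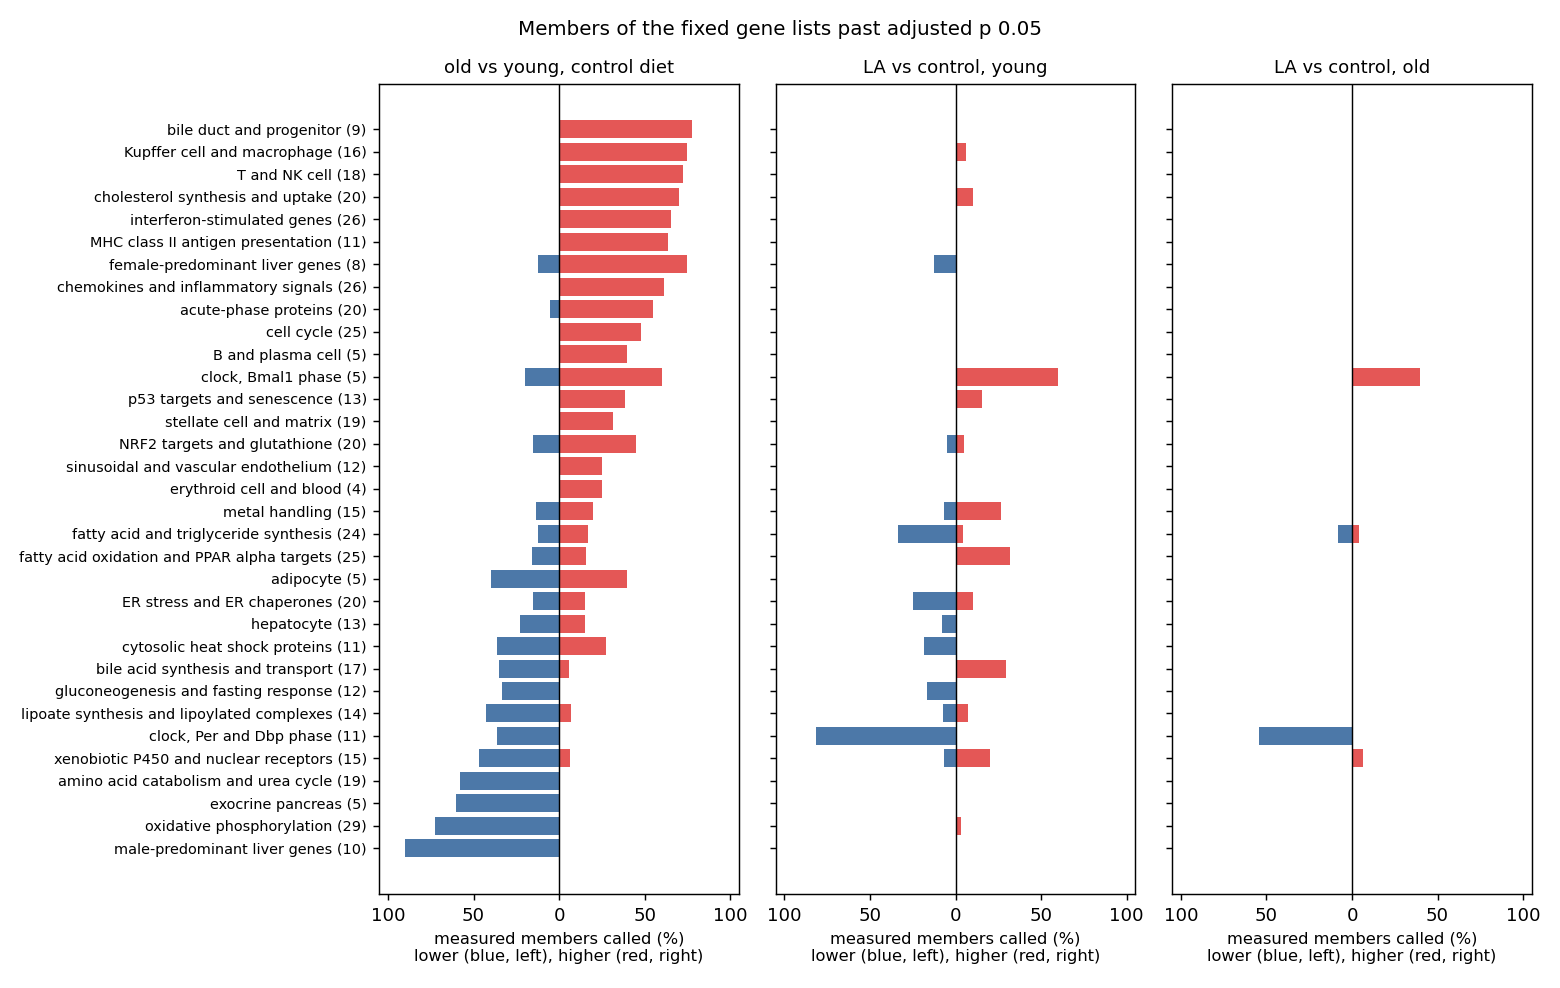
Percent of the measured members (number in parentheses) of each fixed gene list that passed an adjusted p of 0.05, lower to the left and higher to the right, in 3 comparisons. Age moved members of most lists, and LA moved clock genes at both ages.

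The same age comparison on the LA diet asks whether age differences remain under supplementation. Akr1b7 was at least 428-fold higher in old LA than in young LA animals, with Cyp2c12 at 7.39 ± 0.31, and Obp3 and Hsd3b5 lower (-10.91 ± 0.39 for Obp3, at least 636-fold for Hsd3b5). Male-predominant genes fell in 9 of 10 cases (adjusted p = 0.000345 with an estimated correlation) and female-predominant genes rose in 6 and fell in 1 of 8 (adjusted p = 0.0102 with an estimated correlation), with the same counts adjusted over the list alone. Prlr rose by 6.97 ± 0.43, Sult2a2 by 5.76 ± 0.56, the transcription cofactor Trim24 by 4.90 ± 0.42, the myosin Myo7b by 3.95 ± 0.50, Abcc3 by 3.87 ± 0.48 and the protease inhibitor Serpinb9b by 3.86 ± 0.87. Gsta3 was at least 64.6-fold and A1bg at least 19.0-fold higher. Lower genes included Sult1e1 (-8.64 ± 0.49), Slc22a8 (-8.11 ± 0.27), Cyp3a2 (-7.78 ± 0.45), Cyp2c11 (-7.62 ± 0.79), Stac3 (-7.45 ± 0.43), Ust5r (-6.26 ± 0.31), Dhrs7l1 (-6.70 ± 0.62) and the NADPH oxidase Nox4 (at least 43.0-fold lower). Interferon-stimulated genes rose in 22 of 26 cases (24 adjusted over the list alone), including Psmb10 (1.86 ± 0.14) and Herc6 (2.42 ± 0.24), and this list also shifted with an estimated correlation (adjusted p = 0.0244). Chemokine genes rose in 13 of 26 cases (14 adjusted over the list alone), such as Cxcl10 (2.79 ± 0.49) and Il1b (1.74 ± 0.35), with adjusted p = 0.220 with an estimated correlation. Kupffer cell markers rose in 13 of 16 cases, T and NK cell genes in 10 of 18, MHC class II genes in 9 of 11 and acute-phase genes in 8 of 20 (13, 14, 10 and 8 adjusted over the list alone), and oxidative phosphorylation genes fell in 13 of 29 (15). Without old LA 2 the Kupffer cell count was 7, MHC class II 2 (5 without old LA 8) and oxidative phosphorylation 8. For these 5 lists the adjusted p was 0.350, 0.291, 0.397, 0.291 and 0.350 with an estimated correlation. Old LA 2 had the highest T and NK cell score (2.79) and cell cycle score (2.47) of its group. Limma called 2290 genes, 1393 higher and 897 lower, and 1061 higher and 1484 lower with each array centred on its median. Age differences under the 2 diets correlated with r = 0.896 across genes, which are not independent replicates, and 1087 genes were called higher and 681 lower at both diets against 283 and 141 expected from independent lists.

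The comparison of LA-fed with control young animals asks what LA changes in a young liver. Clock genes were among those with the largest changes. The clock activators Bmal1 and Npas2 rose, Bmal1 by 4.46 ± 0.45 from 4.35 ± 0.87 to 8.81 ± 0.21 (SD, n = 8 each) and Npas2 at least 25.0-fold, and Clock rose by 0.96 ± 0.13. Dbp, a clock-controlled transcription factor, fell by 5.49 ± 0.60, Per2 by 3.50 ± 0.40 and the clock repressor Bhlhe40 by 2.62 ± 0.31. Of 11 measured genes of the Per and Dbp phase, 9 fell (10 adjusted over the list alone), and of 5 genes of the Bmal1 phase, 3 rose (3 adjusted over the list alone). Both lists also shifted with an estimated correlation (adjusted p = 0.00123 and 0.0101). Nr1d1 lay at -1.34 ± 0.60 and did not pass (adjusted p = 0.220). The circadian and lipid themes are in the series title and are not independent choices. Times of tissue collection were not given, so a difference in them between the diet groups cannot be told apart from LA.

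**Figure D4:**
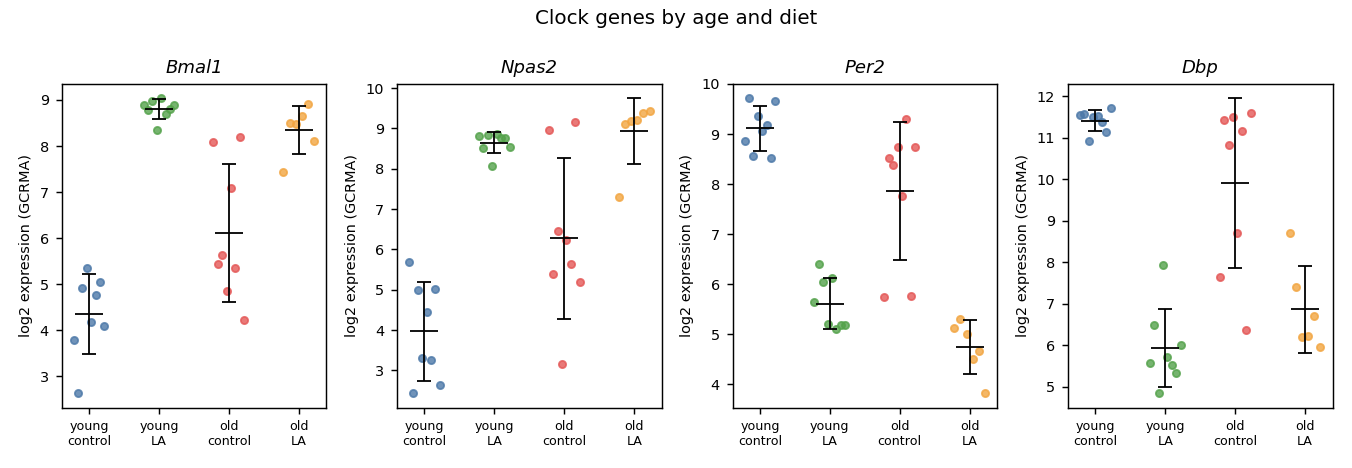
Log2 expression of 4 clock genes on each array (points) with the group mean and SD (black). Bmal1 and Npas2 are higher and Per2 and Dbp lower with LA at both ages, and a pair of old control arrays lies with the LA groups.

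Fatty acid and triglyceride synthesis genes fell with LA in young livers. Of 24 measured, 8 fell and 1 rose (14 and 3 adjusted over the list alone, and 2 higher without young LA 4), with adjusted p = 0.325 with an estimated correlation and 0.0139 with fry. Elovl6, a fatty acid elongase, fell by 3.39 ± 0.60, the lipogenic regulator Thrsp by 3.21 ± 0.37, the desaturase Scd by 2.53 ± 0.42, Fasn by 2.20 ± 0.55 and acetyl-CoA carboxylase, Acaca, by 1.84 ± 0.36. The acyltransferase Agpat2 rose by 0.72 ± 0.11, and Srebf1, which encodes a lipogenic transcription factor, lay at -0.82 ± 0.33 (adjusted p = 0.149). Of 20 cholesterol synthesis genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone), and 1 rose without young control 2, 3, 4, 6 or 8 or young LA 1, 7 or 8 (adjusted p = 0.245 for the list). Fatty acid oxidation and PPARα target genes rose in 8 of 25 cases (9 higher and 1 lower adjusted over the list alone), including the hormone Fgf21 (2.46 ± 0.40), the thioesterases Acot1 (2.80 ± 0.64) and Acot2 (0.97 ± 0.22) and carnitine acetyltransferase, Crat (1.34 ± 0.25), with adjusted p = 0.388 with an estimated correlation and 0.0221 with fry. Cpt1b, a carnitine palmitoyltransferase, rose by 2.85 ± 0.26.

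**Figure D5:**
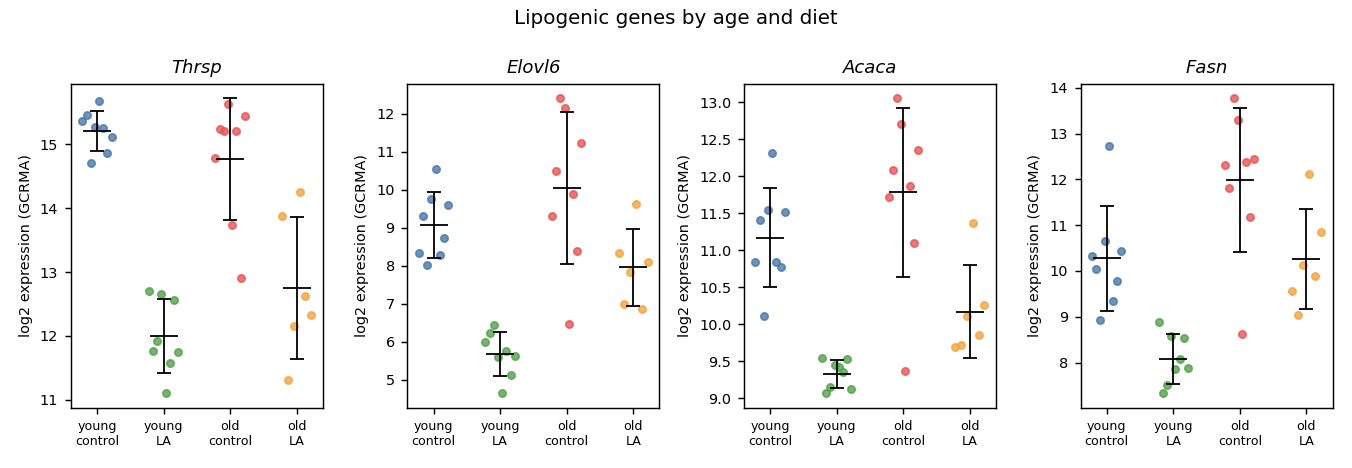
Log2 expression of 4 fatty acid and triglyceride synthesis genes on each array (points) with the group mean and SD (black). All 4 have lower means with LA than with control diet at both ages, and Fasn and Elovl6 did not pass the test in old animals.

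Several other young transcripts responded to LA. The taurine transporter Slc6a6 rose by 4.76 ± 0.50, Poteml2 by 5.47 ± 0.53, the kinase Nim1k by 2.69 ± 0.41, and the nicotinic receptor subunit Chrna2 rose at least 8.58-fold. Rgs16, a regulator of G protein signalling, fell by 4.14 ± 0.72, the fructose transporter Slc2a5 by 3.65 ± 0.38, Fbxl17l1 by 3.45 ± 0.56, the potassium channel Kcnj15 by 3.18 ± 0.61, the steroid dehydrogenase Hsd17b2 by 2.93 ± 0.47 and the deadenylase Noct by 2.65 ± 0.67. In the ER stress list 2 genes rose, Trib3 (2.56 ± 0.48) and asparagine synthetase, Asns (1.73 ± 0.41), and 5 of 20 fell (9 adjusted over the list alone, 2 without young control 1 or 5 or young LA 3, 4 or 5, and 3 without young control 2, 4, 6 or 8), such as the chaperones Hspa5 (-0.42 ± 0.09) and Manf (-0.47 ± 0.12). That list had adjusted p = 0.524 with an estimated correlation. The gluconeogenesis and fasting list was lower, with 2 of 12 genes past the test (4 adjusted over the list alone, and 0 without young control 5 or 6 or young LA 1), Ppargc1a (-0.80 ± 0.23) and pyruvate carboxylase, Pc (-0.41 ± 0.13), whose calls ended in 5 and 14 of 16 fits without 1 array, and adjusted p = 0.0829 with an estimated correlation and 0.00184 with fry. The p53 target Cdkn1a rose by 3.46 ± 0.39 and Sesn2 by 0.85 ± 0.14, the list itself not passing (adjusted p = 0.0582). Amino acid catabolism and oxidative phosphorylation genes passed upward as lists with preset correlation (adjusted p = 0.0391 for each; limma called 0 and 1 members, with 7 and 5 at unadjusted p under 0.05) at means of 0.09 and 0.07, and with an estimated correlation the adjusted p was 0.777 and 0.882. Cyp2c11 (-0.07 ± 0.73), Cyp2c12 (0.28 ± 0.29) and Cd74 (0.20 ± 0.38) did not pass, with adjusted p = 0.991, 0.749 and 0.901. Limma called 677 genes, 338 higher and 339 lower, and 125 exceeded 2-fold (65 higher, 60 lower). Centring each array on its median gave 398 higher and 280 lower, so the even split depends on the scaling. The count of genes changed by lipoic acid, young, was 2030 with array weights, 1718 when the fit held only the young groups, 1068 with all 19762 probe sets and 1320 without old control 5 and old LA 2, whose spread enters the shared estimate, a choice made after seeing the data.

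The comparison of LA-fed with control old animals asks whether an aged liver responds to LA. The clock genes again moved. Per2 fell by 3.13 ± 0.43 from 7.87 ± 1.37 to 4.74 ± 0.54 (SD, n = 8 and 6), Dbp by 3.04 ± 0.65, and Bmal1 and Npas2 rose by 2.24 ± 0.48 and 2.66 ± 0.66. Of 11 genes of the Per and Dbp phase, 6 fell (9 adjusted over the list alone, 3 without old control 4 or 8 or old LA 3, and 2 without old LA 7), among them Tef (-1.59 ± 0.28), Nr1d2 (-1.24 ± 0.27), Per3 (-1.65 ± 0.39) and the deubiquitinase Usp2 (-1.89 ± 0.42), and the list also shifted with an estimated correlation (adjusted p = 0.00299). The Bmal1 phase list had 2 of 5 genes higher (3 adjusted over the list alone, 0 without old LA 7, 1 without old control 2, 3, 4, 6 or 8 or old LA 2, 3, 5 or 8, and adjusted p = 0.135 with an estimated correlation), and Nr1d1 lay at -1.13 ± 0.64 (adjusted p = 0.49). Fatty acid and triglyceride synthesis genes fell in 2 and rose in 1 of 24 cases (10 and 3 adjusted over the list alone). Without 1 array the lower count was 8 (old control 5), 4 (old control 7), 0 (old LA 7) or 1 (old control 2, 3, 4, 6 or 8 or old LA 1, 2, 3 or 8), and the higher count 2 (old control 5) or 0 (old control 3, 4 or 6 or old LA 3, 7 or 8). Of these genes, Thrsp lay at -2.02 ± 0.40, Acaca at -1.62 ± 0.39 and Agpat2 at 0.53 ± 0.12, and the list had adjusted p = 0.420 with an estimated correlation. Elovl6 (-2.09 ± 0.65, adjusted p = 0.117), Fasn (-1.72 ± 0.60, adjusted p = 0.175) and Srebf1 (-0.75 ± 0.35, adjusted p = 0.372) did not pass.

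Outside these groups, LA raised the P450 Cyp3a9 (1.80 ± 0.27), choline kinase, Chka (1.40 ± 0.31), Insig2, a brake on sterol regulatory proteins (1.04 ± 0.18), Tor3a (2.03 ± 0.51), the transcription factor Etv6 (1.08 ± 0.24), Fndc4 (1.16 ± 0.28), Sat2 (0.98 ± 0.20) and Poteml2 (at least 4.39-fold, adjusted p = 0.0384, and 0.0586 with values under 4 raised to 4) in old livers. Slc2a5 fell by 1.90 ± 0.41, the laminin chain Lama3 by 1.83 ± 0.35 and the metalloproteinase inhibitor Timp3 by 1.29 ± 0.28. Interferon-stimulated genes were higher as a list (mean 0.49), but limma called 0 of 26 over all genes, 14 lay at unadjusted p under 0.05 and 8 passed when adjusted over the list alone. Its members Rsad2 (1.49 ± 0.39) and Isg15 (1.15 ± 0.30) had adjusted p = 0.0589 and 0.0594, and the list had adjusted p = 0.135 with an estimated correlation. Amino acid catabolism genes were also higher as a list (mean 0.54), with limma calling 0 of 19, 10 at unadjusted p under 0.05 and 8 adjusted over the list alone, Aass at 0.77 ± 0.20 (adjusted p = 0.0527), and adjusted p = 0.135 with an estimated correlation. With preset correlation the oxidative phosphorylation and erythroid lists passed upward, and the stellate cell, bile duct, acute-phase and endothelial lists downward. Their adjusted p with an estimated correlation was 0.425, 0.194, 0.697, 0.25, 0.589 and 0.697, and limma called 0 members of these 6 lists over all genes, with 7, 4, 4, 2, 1 and 2 at unadjusted p under 0.05. Only the erythroid list had members past the test when adjusted over the list alone (4 of 4). Among old controls, old control 5 had the highest stellate cell (2.54), bile duct (2.11), acute-phase (1.06) and endothelial (1.45) scores. It also had the lowest oxidative phosphorylation (-0.48) and erythroid (-1.51) scores of these controls. The shifts of these lists therefore rest in part on old control 5. Old LA 2 had the highest stellate cell (0.67), bile duct (1.26), acute-phase (0.44) and endothelial (0.37) scores of its group. It also had the lowest oxidative phosphorylation score (-0.25) there, and these values act in the other direction. Its erythroid score (2.56), the highest of its group, acts in the same direction. Cyp2c11 (-0.03 ± 0.79), Cyp2c12 (0.19 ± 0.31) and Cd74 (0.41 ± 0.41) had adjusted p = 0.994, 0.870 and 0.759.

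Limma called 100 genes in old animals, 53 higher and 47 lower, and 23 exceeded 2-fold (9 higher, 14 lower). In simulated data for this contrast 33.1% of the calls were unchanged genes. With only the old groups in the fit limma called 0 (800 genes at unadjusted p under 0.05). That fit holds the same old arrays, and only the estimate of the spread differs. The shared estimate takes in young animals, whose root mean square distance from their group was smaller (0.263 in young and 0.527 in old controls). SEs and adjusted p values of LA in old animals may therefore be too small. This count of genes changed by lipoic acid, old, also depends on which old arrays enter. Without old control 5 and old LA 2, chosen after seeing the data, limma called 379. Leaving out 1 old array at a time gave 10 (without old LA 7) to 321 (without old control 5). Other arrays that moved the count past 1.5 times were old control 1 (158 without it), 3 (63), 4 (52), 6 (60), 7 (180) and 8 (58) and old LA 2 (185) and 3 (46). Array weights gave 192 (77 higher, 115 lower), and array-wise centring on the median gave 83 higher and 41 lower. The calls of Npas2, Acaca, Poteml2, Tor3a, Fndc4, Per3, Agpat2, Etv6, Nr1d2 and Usp2 ended without any 1 of 5 to 10 of the 14 arrays, those of Chka without old control 4, old LA 3 or 7, of Dbp without old LA 3 or 7, and those of Bmal1, Thrsp, Slc2a5, Sat2 and Timp3 without old LA 7.

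The interaction asks whether the LA response differs between ages. Limma called 3 genes, 1 more positive and 2 more negative in old than in young animals, with 694 at unadjusted p under 0.05. The count was 5 without young control 5, young LA 2, old control 2 or old LA 3, and 8 without old control 4 or 5. It was 9 with values under 4 raised to 4, a choice made after seeing the data, and 12 with the replicate number as a block. Nampt, the rate-limiting enzyme of NAD salvage, was lower with LA in young animals (11.95 ± 0.26 to 9.60 ± 0.42, SD) and less so in old (11.48 ± 0.42 to 10.93 ± 0.33), an interaction of 1.81 ± 0.26 (adjusted p = 0.00181). Cpt1b (-2.51 ± 0.39, adjusted p = 0.00231) responded in young animals with no such rise in old ones, whose means were 4.87 ± 0.37 and 5.22 ± 0.44. Chrna2 also passed (adjusted p = 0.00627), but both old means lay under 4, so the size of its interaction is not measured, and with values under 4 raised to 4 it was -2.96 ± 0.56 (adjusted p = 0.0290). The interactions of Bmal1 (-2.22 ± 0.66), Npas2 (-1.57 ± 0.75 with values under 4 raised to 4), Per2 (0.37 ± 0.59), Dbp (2.44 ± 0.89) and Elovl6 (1.30 ± 0.88) had adjusted p = 0.369, 0.767, 0.975, 0.63 and 0.881. Camera called 15 of 33 lists with preset correlation, but 0 with an estimated correlation (3 at unadjusted p under 0.05) and 0 with fry (4 at unadjusted p under 0.05). The LA effects at both ages, which share no array, correlated with r = 0.51 across genes (jackknife SE 0.219 over arrays). Of 100 permutations of the diet labels of old animals, 0 reached that value and 1 reached its size in the negative direction (range -0.53 to 0.49). Of the calls, 33 higher and 34 lower genes were shared, against 1.65 and 1.47 expected from independent lists, and limma called 0 in opposite directions. Over the 677 genes called in young animals, the slope of the old on the young effect was 0.449. These genes were chosen by their young effect, which by itself pulls the slope under 1. The slope therefore does not measure whether old animals respond less.

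Averaged over both ages, LA changed 982 genes, 513 higher and 469 lower. Increases were seen in Bmal1 (3.35 ± 0.33), Slc6a6 (3.27 ± 0.37), Cdkn1a (2.07 ± 0.29), Cyp3a9 (1.88 ± 0.18), the tubulin Tubb2a (1.86 ± 0.26) and Trib3 (1.78 ± 0.35). With values under 4 raised to 4, since some group means lay under it, Poteml2 rose by 3.35 ± 0.29, Npas2 by 3.34 ± 0.38 and Chrna2 by 1.48 ± 0.28. The carboxylesterase Ces1d lay at 1.84 ± 0.59 (adjusted p = 0.0485), and at 1.29 without old control 5, and its call ended in 25 of 30 fits without 1 array. The largest decreases were in Dbp (-4.26 ± 0.44), Per2 (-3.31 ± 0.29), Rgs16 (-3.23 ± 0.53), Slc2a5 (-2.77 ± 0.28), Elovl6 (-2.74 ± 0.44), Kcnj15 (-2.70 ± 0.45), the lipid droplet gene Pnpla3 (-2.66 ± 0.61), Thrsp (-2.61 ± 0.27), Hsd17b2 (-2.32 ± 0.34) and Per3 (-2.09 ± 0.26). Fasn, Acaca and Srebf1 fell by 1.96 ± 0.41, by 1.73 ± 0.26 and by 0.78 ± 0.24, and the call of Srebf1 ended in 14 of 30 fits without 1 array. Fatty acid and triglyceride synthesis genes fell in 13 and rose in 2 of 24 cases (17 and 2 adjusted over the list alone), with adjusted p = 0.279 with an estimated correlation, while the Per and Dbp phase (9 of 11 lower, adjusted p = 0.000685) and the Bmal1 phase (3 of 5 higher, adjusted p = 0.0216) shifted also with an estimated correlation. The count of genes changed by lipoic acid, mean of ages, was 1552 without old control 5 and 1843 with array weights, and centring each array on its median gave 661 higher and 343 lower.

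A further comparison asks whether LA in old animals opposes the age difference. Across genes, the LA effect in old animals and the age effect correlated with r = -0.27 (jackknife SE 0.353 over arrays), where the shared old control arrays alone gave a mean of -0.58 in 100 simulations without effects. The simulated r ran from -0.97 to 0.19, and the simulations held no age difference, so their r is not on the same base as the observed one. The covariance was -0.0494 against a mean of -0.0383 in the simulations (range -0.396 to 0.00896). With the 8 old controls split 4 and 4 the mean r over 70 splits was -0.07 (range -0.37 to 0.46). Ranges this wide do not decide whether LA opposes age. Of genes called in both, 12 were higher with age and lower with LA, and 19 lower with age and higher with LA, and 5 were higher and 12 lower in both. Independent lists would give 9.54, 8.31, 10.8 and 7.37, an expectation that leaves out the shared old controls, which push calls to opposite directions, so these counts do not show that LA opposes age. Old livers differed more from each other than young ones: the root mean square distance of an animal from the mean of the others of its group was 0.527 ± 0.273 in old and 0.263 ± 0.0156 in young controls (SD, n = 8 each, exact permutation p = 0.000155, two-sided). The difference of 0.264 fell to 0.141 without old control 5 (exact permutation p = 0.000155). On the LA diet it was 0.462 ± 0.195 in old and 0.259 ± 0.0301 in young animals (SD, n = 6 and 8, exact permutation p = 0.000333, two-sided), and the difference of 0.203 fell to 0.101 without old LA 2 (exact permutation p = 0.000777). Each of these p values is the smallest its test can give, since every old distance exceeded every young one. The distances were not computed again for permuted labels. Within a group they share arrays, so a far animal also raises the distances of the others, and the p values are approximate. The RNA quality measure, the 5′ minus 3′ signal of control transcripts, differed by -0.125 between old and young controls (exact permutation p = 0.0603, n = 8 each).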

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

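The tests of the 3 patterns below were chosen after their results were seen. Within each group of 6 or 8 animals, the highest and the lowest animal were compared with the rest by Dixon's gap test for named genes, list scores and array measures. Of 614 groups tested, without 10 groups of genes with every value under 4, 64 held an animal apart from the others, 49 for genes, 13 for lists and 2 for array measures, where chance gives about 1 in 20 groups (31 here). Old control 5 stood apart 18 times, old LA 2 9 times, young control 5 6 times and young LA 4 4 times. The root mean square distance from the group was 1.19 in old control 5 (others 0.375 to 0.506) and 0.850 in old LA 2 (others 0.337 to 0.446).

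Abcg8 was 7.95 in young LA 1 (others 6.34 to 6.80), Acaca was 11.37 in old LA 5 (others 9.69 to 10.26) and Akr1b7 was 4.17 in young LA 8 (others under 4), 9.34 in old control 5 (others 12.54 to 13.99) and 7.88 in old LA 2 (others 13.10 to 14.52). Asns was 4.75 in old control 3 (others 7.32 to 8.78), Bhlhe40 was 11.92 in old control 5 (others 8.64 to 10.08) and Ccl5 was 7.49 in young LA 4 (others 7.87 to 8.05). Cdkn1a was 11.34 in old LA 3 (others 10.04 to 10.48), Ces1d was 12.32 in young control 5 (others 13.06 to 13.53) and 2.79 in old control 5 (others 10.99 to 13.11) and Chrna2 was 5.19 in young control 3 (others under 4). Cp was 15.70 in young control 6 (others 15.82 to 15.89) and 15.92 in old control 5 (others 16.22 to 16.41), Crat was 8.75 in old LA 2 (others 9.86 to 10.37) and Cyp2c12 was 8.93 in young control 5 (others 7.24 to 7.72) and 13.61 in old control 5 (others 14.99 to 15.63). Cyp3a2 was 14.87 in young LA 7 (others 15.42 to 15.66) and 10.53 in old LA 2 (others 6.43 to 7.89), Dhrs7l1 was 3.02 in old control 5 (others 6.79 to 9.22) and Fasn was 12.73 in young control 5 (others 8.93 to 10.65).

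Fgf21 was 11.25 in old control 5 (others 7.79 to 9.42), Fndc4 was 5.22 in old control 7 (others 3.65 to 4.33) and Gpnmb was 13.04 in old LA 2 (others 11.02 to 11.72). Gsta3 was 6.60 in old control 5 (others 8.98 to 10.04), Hsd3b5 was 6.91 in old LA 2 (others under 4) and Icam1 was 12.52 in old control 6 (others 10.70 to 11.53). Il1b was 9.58 in old LA 8 (others 7.73 to 8.32), Inmt was 11.06 in young LA 2 (others 11.72 to 12.21) and Insig2 was 14.51 in young LA 5 (others 13.83 to 14.15). Kcnj15 was 6.59 in young control 3 (others 8.15 to 9.35), Manf was 12.56 in young control 3 (others 13.09 to 13.43) and Mcm2 was 8.26 in old LA 2 (others 6.24 to 6.74). Nampt was 11.59 in old LA 1 (others 10.68 to 10.92), Npas2 was 8.07 in young LA 4 (others 8.51 to 8.85) and 7.30 in old LA 1 (others 9.11 to 9.43) and Pc was 10.42 in old LA 7 (others 10.87 to 11.13).

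Per3 was 5.49 in young LA 4 (others 4.50 to 4.95), Pnpla3 was 12.29 in young control 5 (others 5.26 to 8.27) and Poteml2 was 8.12 in young LA 4 (others 9.39 to 10.46). Prlr was 13.26 in old control 4 (others 11.38 to 12.15), Rsad2 was 11.93 in old LA 3 (others 8.96 to 9.84) and Serpinb9b was 3.99 in old control 5 (others 9.76 to 11.76). Tef was 9.31 in young control 7 (others 9.87 to 10.23), Tnfaip3 was 6.28 in young control 6 (others 6.81 to 7.23) and Trim24 was 8.22 in old control 5 (others 11.13 to 11.76) and 9.25 in old LA 2 (others 10.96 to 11.44). Tsx was 6.79 in young control 5 (others 5.02 to 5.62) and 3.49 in young LA 2 (others 4.25 to 4.78). In 4 further groups the gap lay wholly under 4, where signals have no measured order: Akr1b7 at 2.82 in young control 5, Chrna2 at 3.32 in old control 1, Hsd3b5 at 2.59 in old control 4 and Pnliprp2 at 3.32 in young LA 4.

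The bile acid synthesis and transport score was -2.37 in old control 5 (others -0.34 to 0.01), the cell cycle score was 2.47 in old LA 2 (others -0.56 to 0.43) and the cholesterol synthesis and uptake score was 0.52 in young LA 1 (others -0.54 to -0.04) and -0.92 in old control 5 (others 0.17 to 1.03). The clock, Bmal1 phase score was -1.88 in young control 2 (others -1.32 to -0.85), the cytosolic heat shock proteins score was 0.30 in young LA 6 (others -0.27 to -0.01) and the ER stress and ER chaperones score was 0.24 in old LA 7 (others -0.20 to -0.04). The fatty acid and triglyceride synthesis score was 1.25 in young control 5 (others -0.14 to 0.52), the hepatocyte score was -0.25 in old control 5 (others -0.08 to 0.05) and the male-predominant liver genes score was -5.0 in old control 5 (others -3.39 to -2.45). The MHC class II antigen presentation score was 2.66 in old control 5 (others -0.77 to 0.71), the sinusoidal and vascular endothelium score was 1.45 in old control 5 (others -0.23 to 0.24) and the stellate cell and matrix score was 2.54 in old control 5 (others -0.997 to 0.53).

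The LA effect in old minus young animals passed the interaction test for the genes Chrna2 (-3.77), Cpt1b (-2.51), Nampt (1.81). For Chrna2, young controls and both old groups had means under 4, so its size is not measured, and it was -2.96 ± 0.56 with values under 4 raised to 4. With camera at preset correlation it was positive for the lists amino acid catabolism and urea cycle (0.46), clock, Per and Dbp phase (0.55), erythroid cell and blood (0.67), gluconeogenesis and fasting response (0.18), interferon-stimulated genes (0.39), oxidative phosphorylation (0.0732). It was negative for bile duct and progenitor (-0.46), cell cycle (-0.41), cholesterol synthesis and uptake (-0.27), clock, Bmal1 phase (-0.97), fatty acid oxidation and PPAR alpha targets (-0.40), and for p53 targets and senescence (-0.46), sinusoidal and vascular endothelium (-0.23), stellate cell and matrix (-0.49), T and NK cell (-0.52). Camera with an estimated correlation and fry called 0 of these lists, with 3 and 4 at unadjusted p under 0.05. Among old controls, old control 5 had the highest T and NK cell (3.63), stellate cell (2.54), cell cycle (2.36), bile duct (2.11), endothelial (1.45) and p53 (0.61) scores. These scores make the list values more negative. Old LA 2 had the highest of these same scores in its group, among them T and NK cell (2.79) and cell cycle (2.47). This acts in the other direction, so the negative values are not credited to old control 5 alone. The cholesterol synthesis score of old control 5 was instead the lowest of the old controls (-0.92). Clock values of the interaction rest in part on old control 1, 5 and 7, which lay apart from the other old controls. Their Per and Dbp phase scores were -0.49, -0.07 and -0.83, against 0.90 to 1.11 in the other old controls. Their Bmal1 phase scores were 0.43, 0.16 and 0.71, against -1.24 to -0.46.

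Clock genes of 3 control-fed old animals lay past the midpoint of the young groups (-0.29 on an index of Bmal1 phase minus Per and Dbp phase scores): 0.92 in old control 1, 0.23 in old control 5 and 1.54 in old control 7, with the other old controls at -2.35 to -1.45 and the old LA animals at 0.40 to 2.86. An exchange of labels between the old groups needs a partner on the control side, and 0 LA-fed animals lay there. LA fed to animals recorded as controls stays open: 1 of the 3 animals, old control 1, had a lipid synthesis score (0.78) above the range of old LA animals (-1.09 to 0.67), and old control 5 (-1.04) and 7 (-0.16) lay within it. The upper limit rests on old LA 5 alone, and without it the limit is -0.228 and 2 of the 3, old control 1 and 7, lie above it. Tissue taken at another point of the daily cycle in these 3 animals may also give such values and cannot be told apart, since collection times were not given in the sources used here. A difference between old animals in the clock itself was not tested.

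T and NK cell and cell cycle genes were high together in some old animals, with T and NK cell scores of 3.63 in old control 5, 2.79 in old LA 2 and 2.72 in old control 7, and cell cycle scores of 2.36, 2.47 and 1.89. Blood left in the tissue would raise the erythroid score along with the T and NK cell score, but its slope was 0.0215 ± 0.204 over 14 old animals, with -1.51 in old control 5 and 2.56 in old LA 2. The erythroid list held 4 measured genes, and the test takes the ratio of red cells to lymphocytes in blood as equal in all animals. It therefore does not exclude blood as a source. A lower share of hepatocytes would raise markers of the other cell types alike, whereas their slopes on the T and NK cell score ran from 0.167 ± 0.036 for B and plasma cells to 0.534 ± 0.113 for stellate cells. All these slopes were positive, and old control 5 had the lowest hepatocyte score (-0.25) and the highest stellate (2.54) and endothelial (1.45) scores. The hepatocyte score was -0.09 in old LA 2 and 0.02 in old control 7. Slopes also depend on how many members of a list are dim, so the test cannot exclude a part played by the hepatocyte share. Cytotoxic cells other than conventional T cells may be the source, a hypothesis from genes chosen after their values were seen: Gzma, Prf1 and Nkg7 reached 14.20, 14.41 and 13.19 in old control 5, with Cd3e at 5.13 and Cd3g at 4.51, and the median slope of Cd3e, Cd3g, Cd5 and Cd6 on 5 cytotoxic genes was -0.17. Cd8a, a lymphocyte co-receptor, rose with these genes, with a slope of 0.713 ± 0.0777 and 10.80 in old control 5 against 4.39 ± 0.36 in young controls (SD, n = 8). So did Klrb1a and Il2rb, with slopes of 0.955 ± 0.121 and 0.858 ± 0.061. Klrb1a was 12.59 in old control 5 against 5.24 ± 0.45 in young controls (SD, n = 8). Cd8a is not taken here as a marker of T cells alone. The low signal of the 4 probe sets keeps T cells open as a source, and an effect of age itself was not tested apart from the cell source.

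Fatty acid and triglyceride synthesis genes were lower and clock genes shifted with LA in young animals. Lower RNA quality in the LA group would need a lower quality measure there, and the difference was 0.0102 ± 0.0266 (exact permutation p = 0.703, n = 8 each, two-sided), too close to 0 for its spread to decide, and a measure balanced over the groups cannot move the differences as a covariate. Fasting at tissue collection would raise gluconeogenesis and fasting genes, whose mean was -0.21 (adjusted p = 0.0829 with an estimated correlation), and it cannot be told apart from an effect of LA: the labels name a modified pair-feeding scheme, which as a rule matches the amounts eaten, but no times of meals. Fatty acid oxidation and PPARα target genes had a mean of 0.53 in the same contrast, with 8 of 25 higher (adjusted p = 0.388 with an estimated correlation). The gluconeogenesis and fasting list alone therefore does not decide. A clock shift alone as the source of lower lipid synthesis also stays open: of the 3 control-fed old animals with shifted clock genes, 1 had a lipid synthesis score above the range of LA-fed animals, and 2 without old LA 5, which alone sets the upper limit. On the clock index young controls lay at -3.29 to -1.94 and young LA animals at 0.68 to 2.48, with no overlap. Tissue taken at another point of the daily cycle in 1 diet group cannot be told apart from LA, since collection times were not given. LA itself, the difference named by the design, stays among the open explanations.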

How the results depend on the processing

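Leaving out old control 5 and old LA 2 together, raising values under 4 to 4 and leaving out each array in turn for the spread between animals were chosen after the results were seen, and the other alternatives were planned. Settings with all probe sets tested 19762 probe sets in place of 10869 genes, so their counts are not on the same base. For genes changed with age, control diet, taking all probe sets gave 6130. For genes changed by lipoic acid, young, the count was 1068 with all probe sets, 2030 with array weights, 1718 with only the young groups and 1320 without old control 5 and old LA 2. For genes changed by lipoic acid, old, it was 192 with array weights (87 shared), 160 with RNA quality as a covariate, 0 with only the old groups in limma (800 at unadjusted p under 0.05) and 379 without old control 5 and old LA 2 (98 shared). Leaving out 1 array at a time gave 10 (without old LA 7) to 321 (without old control 5). It gave 158, 63, 52, 60, 180 and 58 without old control 1, 3, 4, 6, 7 and 8, and 185 and 46 without old LA 2 and 3. For genes with age by lipoic acid interaction, the count was 12 with all probe sets, 6 with a second quantile normalization, 6 with median centring, 9 with array weights, 9 with values under 4 raised to 4 (3 shared) and 5 without old control 5 and old LA 2. Leaving out 1 array at a time gave 3 to 8 (8 without old control 4 or 5, and 5 without young control 5, young LA 2, old control 2 or old LA 3). For genes changed by lipoic acid, mean of ages, it was 1843 with array weights, 1742 without old control 5 and old LA 2, and 824 to 1552 without 1 array, the highest without old control 5. Fewer genes tested and fewer arrays follow from the construction of some of these settings, and the cause was otherwise not tested.

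With the replicate number as a block the interaction count was 12, with 3 shared. Young control and young LA animals of the same number correlated above 0.1 in 7 of 8 pairs (lowest 0.0706), and 8 of 8 correlated best with their own number, a hint from the data, not the design, at a shared factor. Against old controls, 4 of 8 young controls and 4 of 8 young LA animals also correlated best with their own number. Against old LA animals it was 1 young control and 0 young LA animals. Between old control and old LA animals the median was -0.22 for the same number and 0.154 for other numbers, with 1 of 6 pairs above 0.1. Pair-feeding, which the labels name without partners, may be a factor in the young pairs, but within an age it would not link young with old animals. Whether the numbers mark it stays open. Lists shifted with an estimated correlation numbered 2 for age on the control diet, 2 for LA in young animals, 1 for LA in old animals, 3 for age on the LA diet, 0 for the interaction and 2 for the mean LA effect. With fry they were 24, 7, 5, 17, 0 and 11 in the same order, where camera with preset correlation called 20, 8, 11, 19, 15 and 9 (for the interaction 3 lists with an estimated correlation and 4 with fry at unadjusted p under 0.05), and without old control 5 and old LA 2 the interaction had 7.

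Direction turned for 4 differences of named genes. Apob, age_control went from 0.27 to -0.46 with the mean of its probe sets. Srebf1, age_control was 0.05, and -0.0622 with median centring, -0.26 with RNA quality, and -0.0592 to 0.29 without 1 array. Cyp2c11, LA_old was -0.03, and 0.0366 with a second quantile normalization, 0.0025 with median centring, 0.22 with array weights, 0.20 with RNA quality, 0.17 without old control 5 and old LA 2, and -0.76 to 0.63 without 1 array. Cyp2c12, LA_old was 0.19, and -0.0228 to 0.29 without 1 array. The cause was not tested. Of 198 means of lists, 33 lists in 6 contrasts, 4 turned with a second quantile normalization and 10 with median centring, none of them called by camera and none larger in size than 0.0634 in the main fit. Of the values of named genes under alternatives, 3853 of 3945 kept direction and side of the threshold for age on the control diet, 1746 of 1820 for LA in young animals, 614 of 753 for LA in old animals, 2652 of 2752 for age on the LA diet, 123 of 123 for the interaction and 2891 of 3074 for the mean LA effect. The agreement of lipoic acid effects between ages (r 0.469 to 0.551) and the lipoic acid effect in old against the age effect (r -0.388 to -0.232) kept their direction. These ranges leave out the fits without 1 array, which entered only the jackknife SE (0.219 and 0.353). The second SE is larger than the size of its r in the main fit (-0.27). The spread between animals also kept its direction. Its difference was 0.107 with the median absolute distance, 0.141 without old control 5 and at most 0.300. Probe sets near the floor limit folds to lower bounds and leave changes of dim genes unmeasured.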

Other observations

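The counts over other splits of the animals were planned before the results were seen, and the relation between list scores was chosen after. In young livers LA changed 5 of 17 bile acid synthesis and transport genes, all higher, with a list median of -0.01, a mean of 0.14 and adjusted p = 0.088, and 3 of them without young control 2. Of 15 metal handling genes 4 rose and 1 fell (adjusted p = 0.245), and 1 rose without young control 5 and 2 without young control 6 or young LA 3, 5 or 8, and of 15 xenobiotic P450 genes 3 rose and 1 fell (adjusted p = 0.316). In old animals on the LA diet against young ones, 3 of 4 erythroid genes were higher (mean 1.47, adjusted p = 0.0142, and 0.291 with an estimated correlation), and 4 of 9 bile duct and progenitor genes were higher (mean 0.94, adjusted p = 0.0152, and 0.350 with an estimated correlation), and 2 without old LA 2.

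Over 14 old animals the T and NK cell score and the cell cycle score correlated with Pearson r = 0.93 (permutation p = 1e-05, the smallest the draws can give, adjusted p = 3e-05) and Spearman rho = 0.855 (permutation p = 0.00018, adjusted p = 0.00054), over a family of 3 relations. Without old control 5 and old LA 2, r was 0.882 (permutation p = 1e-04) and rho 0.776 (permutation p = 0.00424). Among 8 old controls r was 0.947 (exact p = 0.00144, adjusted p = 0.00216) and rho 0.691 (exact p = 0.0694), and without old control 5 and 7 r was 0.781 (exact p = 0.114) and rho 0.257 (exact p = 0.658). Among 6 old LA animals r was 0.925 (exact p = 0.00417) and rho 0.943 (exact p = 0.0167, adjusted p = 0.025).

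Chance was counted as excluded where fewer than 5 of 100 splits of the animals, the real one included, gave a count as large. That held for genes changed with age on the control diet (1 split as large, 3911 genes against 589 at most in another) and with LA in young animals (1 split, 677 against 92). It also held with age on the LA diet (1 split, 2290 against 521) and in the mean LA effect (1 split, 982 against 2). The interaction met the same rule (2 splits), but another split called 9 genes against the real 3. Its splits move diet labels within each age and so also remove the LA effect shared by both ages. They cannot decide whether the 3 genes arose by chance. For genes changed with LA in old animals chance was not excluded (5 splits as large, 100 against 1004). The split that called 1004 genes, many times the real count, points to a structure of the samples, and its cause was not tested. The 4 other splits that called 154 to 1004 genes put old control 5 and old LA 2 in 1 group, but so did 42 of all the other splits. For lists, age on the LA diet met the rule (2 splits as large), but the other split called as many (19 against 19). Chance was not excluded for lists with age on the control diet (5 splits, 20 against 22), LA in young animals (9 splits, 8 against 11), LA in old animals (41 splits, 11 against 18), the interaction (8 splits, 15 against 18) or the mean LA effect (43 splits, 9 against 18).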
